A study of Drosophila melanogaster with 16 samples.

How the data were processed

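Total RNA of dissected ring glands was extracted with TRIzol and a column kit, made into libraries with the NuGEN Encore Complete kit and sequenced on an Illumina HiSeq, per the labels' protocols. Larvae were kept at 25 °C under 12 h of light and 12 h of dark. The series has 16 libraries in 8 conditions, 2 biological samples per condition, and every library was assigned to its condition from its title. The deposited table lists 15771 genes and gives average RPKM values per condition, computed by the authors, per the file headers. It holds no value per library and no read counts, so the depth and the spread between replicates are unknown, and no interval could be given for any gene's value or difference. A second block of columns holds signed fold changes (a score that is the ratio where it is at least 1 and minus its inverse otherwise) made by the authors, per the file headers. Those fold scores equalled the ratio of the authors' averages within 0.169% for genes above 0.5 RPKM. In the column named for control day against control night the ratio was night over day. A value of 0 had been replaced by a constant of 0.000228 in these ratios. The aligner, the counting tool, the genome build and the annotation of the deposited table are not given in the sources used here, nor is how the averages were formed.

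Gene symbols were used as the table gives them. Identifiers were matched to the Ensembl release 115 annotation of BDGP6 by FlyBase identifier for 15177 genes and by symbol for 201, 15378 in all, and positions come from that annotation. Values are printed as the authors' means, with no SD or n. A total of 2282 genes, 1156 of them protein-coding, were listed at 0 in every condition, among them the immune genes Rel, Def and Mtk and the glue gene Sgs4, so a 0 was read only as listed at 0. No fold is given against a 0.

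The tests fixed before the data were examined were limma fits on log2(RPKM + 1) over 16 libraries, camera tests of gene lists and interaction terms. None could be run on 1 average per condition. In their place a rule of size was used, chosen once the table was seen to hold only averages: a gene counted as higher or lower where the difference of log2(RPKM + 1) was at least 2, that is 4-fold. This pseudocount of 1 understates differences of low genes. Genes entered where at least 1 of the 8 conditions reached 1 RPKM, which left 12843 genes, 11925 of them protein-coding. The 10 pairwise comparisons were control night against day, 6 genotype comparisons with the control of the same time, both RNAi genotypes at night against day, and overexpression of both genes against tim alone. A pair of double differences (night minus day in an RNAi genotype less that in control) was given as values for tim, per and ecdysone biosynthesis genes.

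The 32 gene lists, from pathways of the gland to markers of neighbouring tissues, were fixed before the data were examined. Of their members 557 were found in the table and 7 were not, among them the ecdysone gene spok. For each list the median difference was placed among the medians of 10000 random lists of protein-coding genes matched on mean level in 60 bins, with limits at percentiles 2.5 and 97.5. This describes these averages and is no test across animals. Over 224 pairs of list and comparison, 51 lay outside the limits. Lists of independent genes would do so in about 1 in 20 pairs. Members of these lists can vary together and the comparisons share control averages, so the 51 cannot be read as an excess over chance.

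The values were used as deposited, and scaled in 4 other ways: by the median ratio over all genes, by quantile normalization, on the 500 protein-coding genes of highest mean level, and on those genes after subtracting the median of 185 chemoreceptor genes. Other alternatives were a pseudocount of 0.1, no filter, and a mean RPKM of at least 5. Abundant-gene scaling, its use after the subtraction and its use with the stricter filter were added after the data had been seen.

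Named genes followed a rule fixed beforehand: tim and per, up to 6 ecdysone biosynthesis genes per comparison, the 8 highest and 8 lowest genes of at least 5 RPKM that have a proper name, and up to 4 members per list past the threshold (for the 3 other pairs, 4 and 2 members). The parts of the rule that asked for adjusted p-values and for replicates that do not overlap could not be applied, and size alone ranked the genes. Values of Fbp1 in control night against day and in tim RNAi day, of phm in the day libraries labelled per RNAi and in tim overexpression, and of nvd in tim and per overexpression were chosen after the values had been seen. Histone, Stellate, Hsp70, glue, Jonah and cuticle genes have close copies among which reads can be split, so their values are uncertain.

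Before use, the scaling and list steps were tested on simulated data of 11925 genes, read as control night against control day. Each gene had 1 true level taken from all 8 conditions, with independent noise and 1 scale factor per condition. Of 53 genes of at least 5 RPKM changed 8-fold, 48 were past 4-fold after abundant-gene scaling, and 0 unchanged genes were. Of 400 unchanged lists 17 lay outside the limits, and 20 of 20 changed lists lay above them. In the simulation silent genes did not shift apart from expressed ones, and list members did not vary together. Its results therefore do not cover those features of the deposited values. Intervals of ratios of medians over genes, in the closing part, are 95% bootstrap intervals over genes from 2000 resamples. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9 and random seed 11.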

Results

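RNA from ring glands of third-instar Drosophila melanogaster larvae was sequenced in 8 conditions. The ring gland is the compound endocrine organ of the larva and joins the prothoracic gland, which makes ecdysone, with the corpora allata, which make juvenile hormone, and the corpora cardiaca, which make adipokinetic hormone. The driver phantom-Gal4 is active in prothoracic gland cells and was used alone (control), with RNAi against the clock genes timeless (tim) or period (per), or with overexpressed cDNA of tim or of tim and per together. Control, tim RNAi and per RNAi glands were sampled by day (Zeitgeber time 0 to 4 h) and at night (18 to 22 h), and both overexpression genotypes at night only. The day samples were 2 to 4 h into the third instar and the night samples 18 to 20 h into it, so time of day and larval age changed together. The series holds 16 libraries, 2 per condition, and the deposited table gives 1 average RPKM (reads scaled by gene length and library size) per gene and condition. No difference reported here has a replicate check, and the read depth per library is unknown.

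Expressed and silent genes sat at very different distances from each other in the 8 conditions. The median of the cytosolic ribosomal protein genes, which every cell uses, was 41.0 RPKM in control day, 660 in control night, 375 in tim RNAi day, 249 in the day libraries labelled per RNAi, 249 in tim RNAi night, 85.9 in the night libraries labelled per RNAi, 515 in tim overexpression and 203 in tim and per overexpression. For 185 odorant, gustatory and ionotropic receptor genes, which belong to sensory neurons, the medians in the same order were 1.10, 0.006, 1.26, 0.014, 0.459, 1.604, 0.747 and 1.99 RPKM. Their 95th percentile, taken as the level below which a gene cannot be told from silent genes, was 2.34, 0.26, 2.35, 0.589, 0.947, 4.87, 1.33 and 3.13 RPKM. The 10 most abundant genes, mostly non-coding annotations and in each condition headed by 1 of them, held between 33.5% of the summed RPKM, in the night libraries labelled per RNAi, and 85.0%, in tim RNAi night. Those genes held 64.4% of the sum in control day and 64.5% in control night, with sums of 190639 and 713430 RPKM.

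**Figure D1:**
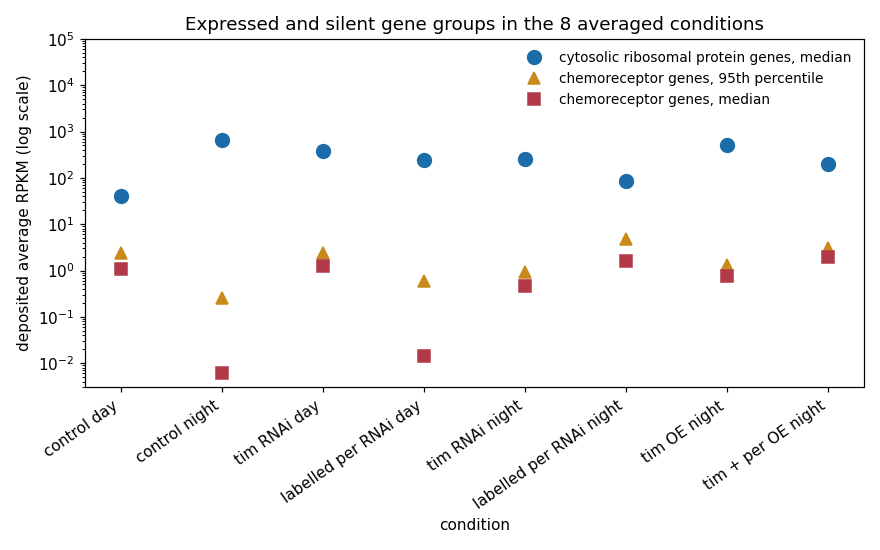
Median deposited RPKM (log axis) of cytosolic ribosomal protein genes (circles) and of 185 chemoreceptor genes (squares) with the 95th percentile of the latter (triangles), for each of the 8 averaged conditions on the x axis. Chemoreceptor medians ran from 0.006 RPKM in control night to 1.99 in tim and per overexpression, and ribosomal protein medians from 41.0 in control day to 660 in control night.

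Because of these shifts, differences are given as log2 of (RPKM + 1) as deposited, followed by the value after scaling each condition on the 500 most abundant protein-coding genes. Ribosomal protein genes are at the level of that set, so this scaling pulls their list towards 0 by construction. How many of them it holds was not counted. The log2 scale factors of the latter were -1.75 for control day, 1.20 for control night, 0.71 for tim RNAi day, -0.09 and -0.28 for the day and night libraries labelled per RNAi, -0.21 for tim RNAi night, 0.80 for tim overexpression and -0.23 for tim and per overexpression. Median-ratio factors over all genes in the same order were 0.14, -0.24, 0.55, -0.80 and 1.15, -0.61, 0.08 and 0.32. Whether a direction held is stated over 5 scalings, which are the deposited values, median-ratio, quantile, abundant-gene scaling, and abundant-gene scaling after subtracting the chemoreceptor median. Values between 0 and 0.2 RPKM form a separate low group that also held transcripts abundant elsewhere, so those printed for per, ng3, PGRP-SC1a, IM2, IM4, Dpt, DptB, Lcp65Ab1 and Ste:CG33246 are uncertain. The chemoreceptor medians of 0.006 RPKM in control night and 0.014 in the day libraries labelled per RNAi lie in that group and are uncertain too. Values under 1 RPKM of genes abundant in other conditions are uncertain in the same way, as for RpL41, RpL37A, smt3, Hsp70Bb, IM1, Snap25, Sgs1, Sgs3, Sgs8, Eig71Ee and Fbp1.

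The targeted genes came first because they check the labels. The gene tim (FBgn0014396, BDGP6 chromosome arm 2L, 3493986 to 3508119, minus strand), whose protein partners PER in the clock's negative loop, was at 1.88 RPKM in control day and 1.71 in tim RNAi day. At night tim stood at 1.38 RPKM in control, 1.09 in tim RNAi, 9.46 in tim overexpression and 9.19 in tim and per overexpression. The day values lay below the 95th percentile of silent genes, so a knockdown of tim was not detectable by day, and the night difference of tim RNAi flipped from -0.19 as deposited to 0.49 on the abundant-gene scale. The gene per (FBgn0003068, X chromosome, 2685580 to 2692780, plus strand) was at 1.59 RPKM in control day and 0.411 in the day libraries labelled per RNAi, both below that percentile. In the night libraries labelled per RNAi, per was at 2.85 RPKM against 0.067 in control night, which as printed is the opposite of the label, although 2.85 lay below their silent-gene limit of 4.87 and cannot be told from silent genes. In the same libraries tim was at 6.79 RPKM, above that limit. With tim and per overexpressed, per reached 10.3 RPKM, and it was 0.97 with tim alone.

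Control night against control day asks how the gland's transcripts differed between the light and dark phases, with larval age as a second difference. Genes of ecdysone synthesis were split. The gene sad, a mitochondrial P450 that makes ecdysone from its direct precursor, was at 883 RPKM at night and 59.9 by day, a log2 difference of 3.86 as deposited and 0.93 on the abundant-gene scale, and was higher in all 5 scalings. The P450 gene phm was higher in all 5 as well, at 253 against 30.1 RPKM (3.03 and 0.12). For dib, another P450 of the pathway, 41.9 against 6.92 RPKM gave 2.44 as deposited but -0.33 on the abundant-gene scale. The gene nvd, which takes the pathway's first step from cholesterol, was lower in all 5 scalings at 2.21 against 5.48 RPKM (-1.01 and -3.30), and sro flipped from 1.00 to -1.81. Neither sad nor phm exceeded the difference of Akh, the hormone of the corpora cardiaca: Akh was at 1517 against 76.7 RPKM (4.29 and 1.35) and jhamt, the last enzyme of juvenile hormone synthesis, at 257 against 16.1 (3.91 and 1.03).

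Other gene groups were compared between night and day glands in the same way. Of 91 cytosolic ribosomal protein genes, 82 were past 4-fold higher and 1 lower as deposited, with RpL6 at 910 against 19.9 RPKM, and on the abundant-gene scale 3 were higher and 5 lower, with a list median of 0.93, positive in all 5 scalings, and a percentile of 100 as deposited that fell to 72.5 under another setting. Among fat body products, some were high at night, with Fbp2 at 920 against 21.7 RPKM (5.35 and 2.45), Lsp1beta at 1667 against 61.7 (4.73 and 1.80) and Lsp2 at 1105 against 65.4 (4.06 and 1.13), in all 5 scalings. Fbp1 went the other way, at 2.16 against 10.6 RPKM (-1.88 and -4.24). The fat body list lay within the limits at percentile 93.6, with a median of 3.60 that was positive in all 5 scalings. Of its 9 members 6 were past 4-fold higher and 0 lower as deposited, and 1 higher and 2 lower on the abundant-gene scale. Nplp2, annotated as a neuropeptide-like precursor, was at 6064 against 105 RPKM (5.84 and 2.90), and Obp99b, an odorant-binding protein, at 3980 against 82.4 (5.58 and 2.64). Lower at night in all 5 scalings were the histone gene His4:CG31611, at 3.19 against 372 RPKM (-6.48 and -9.03), and toy, an eye determination factor, at 1.99 against 72.9 (-4.63 and -7.04). Histone genes are repeated in near-identical copies, so values of single copies are uncertain. The lists of midgut digestion (median 0.04 as deposited, percentile 0.01), salivary gland (0.33, percentile 0.1), heat shock (-0.05, percentile 1.81) and mitochondrial respiration (1.97, percentile 0) lay below random lists of the same expression, with medians that changed sign over the scalings, and that of the salivary gland reached percentile 2.53 under another setting. Of 34 mitochondrial respiration genes, 17 were past 4-fold higher and 0 lower as deposited, and 0 and 9 on the abundant-gene scale. Random lists at that level can hold ribosomal protein genes, whose share was not counted. Ecdysone biosynthesis (median 0.15, percentile 10.9) and the core clock (-0.53, percentile 63.3) lay within. Of the 8 ecdysone biosynthesis genes, spo, shd and Cyp6t3 lay near or under the silent-gene limit in most conditions. Medians and percentiles of that list therefore rest in part on genes that cannot be told from silent ones, here and below. As deposited, 889 genes were past 4-fold higher and 231 lower of 12843. That split was 119 and 226 after quantile normalization, 45 and 7449 on the abundant-gene scale, and 52 and 2388 with the silent-gene level subtracted as well.

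**Figure D2:**
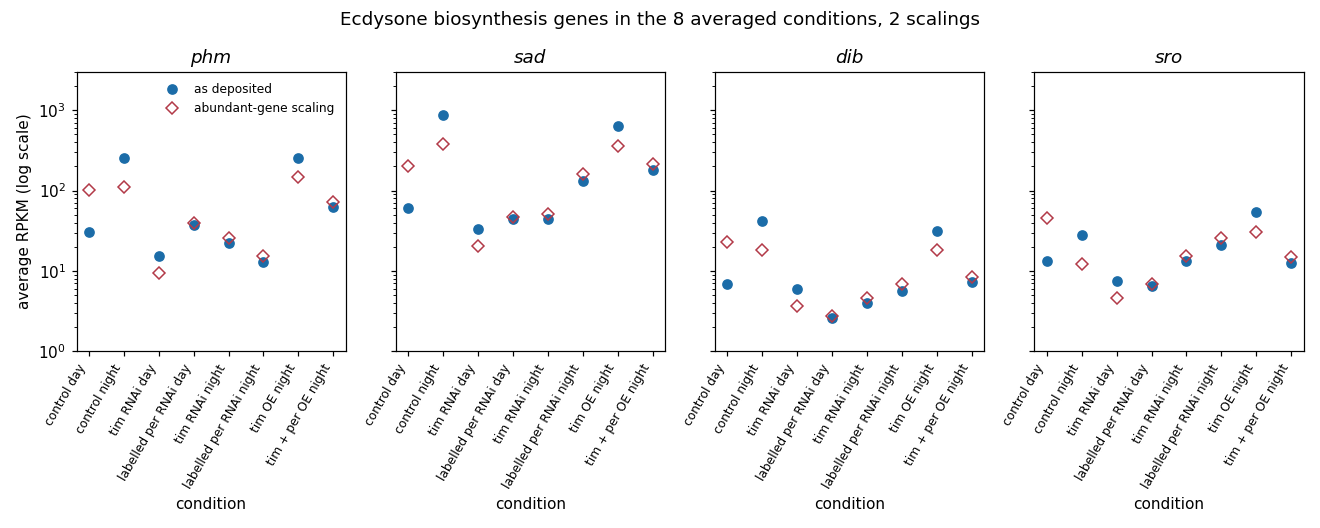
Average RPKM (log axis) of phm, sad, dib and sro in the 8 conditions on the x axis, as deposited (filled circles) and after abundant-gene scaling (open diamonds). As deposited sad was at 883 RPKM in control night against 59.9 in control day, while dib, at 41.9 against 6.92, flipped to -0.33 (log2) after scaling; tim RNAi night was low for sad, at 44.5 RPKM, under both.

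tim RNAi against control by day asks what loss of tim in the prothoracic gland does in early third-instar glands, although no loss of tim transcript was detectable. Ecdysone genes were lower in all 5 scalings: phm at 15.3 against 30.1 RPKM (-0.93 and -3.30), sad at 33.6 against 59.9 (-0.82 and -3.23), sro at 7.60 against 13.5 (-0.75 and -3.03) and nvd at 3.21 against 5.48 (-0.62 and -2.71). The list of ecdysone biosynthesis, 8 members, had a median of -0.41 as deposited, at percentile 0.01 of random lists, with 0 members past 4-fold in either direction as deposited and 5 lower on the abundant-gene scale. Prothoracic gland transcription factors had a median of -0.15 at percentile 0.04. Antimicrobial peptide genes went the other way: Dro was at 206 against 2.84 RPKM (5.76 and 3.59), Drs at 124 against 2.02 (5.37 and 3.30), AttC at 104 against 2.30 (4.99 and 2.89) and IM2 at 153 against 4.60 (4.78 and 2.52). Of 21 innate immunity genes, 15 were past 4-fold higher and 0 lower as deposited, and 11 and 1 on the abundant-gene scale, with percentile 100 under every setting run.

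Salivary glue genes were low in the same glands. Sgs5 was at 1.497 against 58.2 RPKM (-4.57 and -6.68), Sgs8 at 3.37 against 85.7 (-4.31 and -6.56), Sgs7 at 16.2 against 251 (-3.87 and -6.27) and Sgs3 at 0.966 against 34.6 (-4.18 and -6.20), and the salivary gland list was at percentile 0 in all settings, with 5 of 8 members past 4-fold lower. The member past 4-fold higher was ng3, at 76.7 against 0.077 RPKM. Gut proteases were high, with Jon65Aiv at 2047 against 31.2 RPKM (5.99 and 3.57), yip7 at 821 against 15.0 (5.68 and 3.29) and Jon65Aiii at 848 against 23.5 (5.12 and 2.70). The midgut list (median 1.98, percentile 97.7) had 6 of 13 members past 4-fold higher and 0 lower as deposited. On the abundant-gene scale 2 were higher and 2 lower and its median was -0.38, and its percentile was as low as 94.4 under other settings. Lsp1beta, from fat body, was at 1364 against 61.7 RPKM (4.44 and 2.00), Mp20 and Mlc2, from muscle, at 363 against 25.8 (3.76 and 1.34) and at 354 against 36.0 (3.26 and 0.83), and Cha, from cholinergic neurons, at 34.8 against 2.43 (3.39 and 1.28). Their lists lay within the limits, at percentiles 21.9 for fat body, 92.0 for muscle and 10.2 for neurons, and Fbp1 was lower, at 3.40 against 10.6 RPKM. Medians of the lists of PTTH and MAPK pathway (0.00, percentile 2.42), juvenile hormone (0.03, percentile 0.88), hemocytes (0.08, percentile 0.5) and mitochondrial respiration (1.93, percentile 0.39) were below random lists, and that of brain neuropeptides (1.09, percentile 99.6) above. Of these 5, the medians of juvenile hormone (-1.63 on the abundant-gene scale), hemocytes (-1.96), mitochondrial respiration (-0.42) and brain neuropeptides (-1.13) flipped, and percentiles came back within the limits under some settings, up to 6.99 for the PTTH and MAPK pathway, 24.2 for juvenile hormone, 46.3 for hemocytes and 33.0 for mitochondrial respiration, and down to 62.0 for neuropeptides. As deposited, 739 genes were past 4-fold higher and 51 lower. The split was 249 and 199 after quantile normalization, 108 and 2394 on the abundant-gene scale and 134 and 1893 with subtraction.

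Day libraries labelled per RNAi against control day had low levels of glue genes. Sgs7 was at 1.94 against 251 RPKM (-6.42 and -8.11), Sgs8 at 0.867 against 85.7 (-5.54 and -7.23), Sgs3 at 0.324 against 34.6 (-4.75 and -6.44) and Sgs1 at 0.840 against 42.9 (-4.57 and -6.26). The salivary gland list was at percentile 0, with 5 of 8 members past 4-fold lower and 1, ng3, higher. Eig71Ee, an ecdysone-induced gene, was at 0.394 against 19.4 RPKM (-3.87 and -5.54), and Fbp1, an ecdysone-induced fat body protein, at 0.560 against 10.6 (-2.90 and -4.52). Ecdysone synthesis genes were lower in all 5 scalings for dib, at 2.58 against 6.92 RPKM (-1.15 and -2.70), and for nvd, at 1.92 against 5.48 (-1.15 and -2.67), but phm flipped, at 37.3 against 30.1 (0.30 and -1.33). Their list was at percentile 4.89, inside the limits, with a median of -0.66, and from 0.01 to 8.87 over the settings run.

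Muscle and gut transcripts were high in those day libraries labelled per RNAi. Act57B was at 1317 against 58.1 RPKM (4.48 and 2.84) and Mlc1 at 120 against 13.8 (3.03 and 1.44), with 6 of 13 muscle genes past 4-fold higher as deposited (median 1.80, percentile 99.3) and 1 on the abundant-gene scale (median 0.22). The protease genes Jon25Bii, at 162 against 7.21 RPKM (4.31 and 2.78), and Jon99Cii, at 2858 against 173 (4.04 and 2.39), were among 6 of 13 midgut genes past 4-fold higher as deposited, at percentile 100, and 4 were higher and 1 lower on the abundant-gene scale. Lcp65Ag2, a larval cuticle protein, was at 470 against 13.9 RPKM (4.98 and 3.39). Of 91 ribosomal protein genes 70 were past 4-fold higher and 0 lower as deposited (median 2.49, percentile 99.7, down to 79.4 over the settings), and 3 and 4 on the abundant-gene scale. Innate immunity split, with PGRP-SC1a at 14.4 against 0.057 RPKM and IM4 at 0.059 against 5.22. Its median of 0.09 (percentile 99.98) became -1.24 on the abundant-gene scale, and brain neuropeptides (0.39, percentile 99.9) and oxidative stress (0.31, percentile 99.2) flipped likewise. Their percentiles fell within the limits under other settings, to 62.2, 87.6 and 76.0. Below random lists lay fat body (-0.14, percentile 0.28), sterol uptake (-0.70, percentile 0.25), prothoracic gland transcription factors (-0.88, percentile 0.29), ecdysone response (-1.0, percentile 0.355) and the PTTH and MAPK pathway (-0.82, percentile 1.87). Of these, fat body and sterol uptake changed sign over the scalings. Fat body alone stayed outside in all settings, the others reaching percentiles of 94.0 for sterol uptake, 53.1 for the transcription factors, 16.4 for ecdysone response and 29.2 for the PTTH and MAPK pathway. In all, 326 genes were past 4-fold higher and 124 lower as deposited, 733 and 63 after median-ratio scaling, 181 and 141 after quantile normalization, 82 and 5428 on the abundant-gene scale and 109 and 1215 with subtraction.

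**Figure D3:**
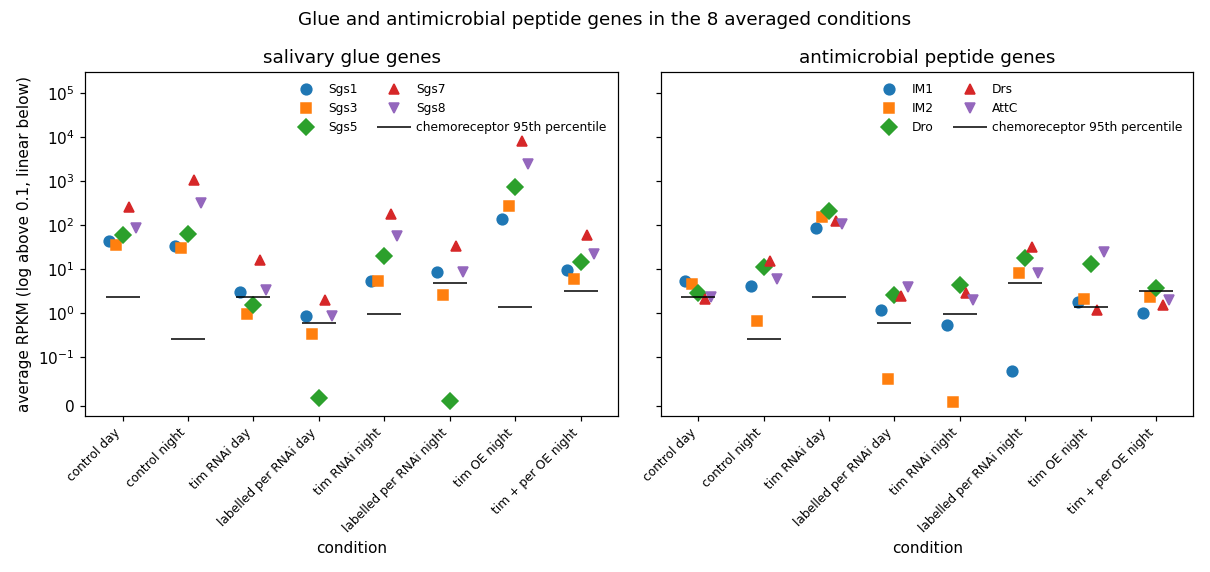
Average RPKM (log axis above 0.1, linear below) of 5 salivary glue genes (left) and 5 antimicrobial peptide genes (right) in the 8 conditions, with the 95th percentile of chemoreceptor genes as a dash. Sgs7 ran from 1.94 RPKM in the day libraries labelled per RNAi to 8266 in tim overexpression, and Dro reached 206 RPKM in tim RNAi day against 2.84 in control day; both directions held in all 5 scalings.

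tim RNAi against control at night compares the same genotypes in older glands, again with no loss of tim transcript detectable. Ecdysone synthesis genes lower in all 5 scalings were sad at 44.5 against 883 RPKM (-4.28 and -2.88), phm at 22.2 against 253 (-3.45 and -2.06) and dib at 4.01 against 41.9 (-3.10 and -1.77). GstE14, the glutathione transferase noppera-bo that acts in sterol supply to this pathway, was at 11.8 against 181 RPKM (-3.83 and -2.45), Start1, a putative sterol carrier, at 5.64 against 58.8 (-3.17 and -1.82), Npc1a, the intracellular sterol transporter, at 3.47 against 19.4 (-2.19 and -0.92) and sna, a zinc-finger factor, at 2.59 against 26.4 (-2.93 and -1.65), all in the same direction in the 5 scalings. The vvl gene, a POU factor of the prothoracic gland, was at 24.9 against 110 RPKM (-2.10 and -0.72). Among 8 ecdysone biosynthesis genes 3 were past 4-fold lower and 0 higher as deposited, and 2 and 0 on the abundant-gene scale. The list's median of -0.61, which became 0.42 on that scale, lay at percentile 62.2 as deposited, but between percentiles 0 and 69.6 over the settings run, and sro flipped from -1.0 to 0.33. In tim RNAi night the members spo, shd and Cyp6t3 were at 0.92, 0.495 and 0.953 RPKM, against a silent-gene limit of 0.947. In control night they were at 0.277, 0.253 and 0.283 RPKM, against 0.26. This median therefore rests in part on genes near the silent-gene level.

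Beyond that pathway, Pk17E, a putative protein kinase gene, was at 2.03 against 146 RPKM (-5.60 and -4.27) and obst-A, a chitin-binding matrix protein, at 7.04 against 322 (-5.33 and -3.95). Hsp22 was listed at 0 against 16.2 RPKM. Higher at night with tim RNAi were Fbp1, at 12.0 against 2.16 RPKM (2.04 and 2.93), Jon99Ciii, a gut protease, at 1170 against 385 (1.6 and 3.0), and ng3, at 145 against 41.9 (1.76 and 3.12). Medians of fat body (-0.11, percentile 100), midgut (-0.22, percentile 99.96), oxidative stress (-0.18, percentile 99.98) and innate immunity (-0.27, percentile 98.7) stood above random lists and turned positive on the abundant-gene scale, with 1.29 for fat body and 0.97 for midgut. Innate immunity came back within the limits under other settings, down to percentile 10.2. The salivary gland list was below them in all 5 scalings (-1.91, percentile 0), Sgs7 being at 174 against 1031 RPKM (-2.56 and -1.15). As deposited 4 of its 8 members were past 4-fold lower and 0 higher, whereas on the abundant-gene scale, with a median of -0.57, 0 were lower and 1 higher. As deposited, 21 genes were past 4-fold higher and 180 lower. The split was 45 and 100 after median-ratio scaling, 49 and 41 after quantile normalization, 80 and 34 on the abundant-gene scale and 74 and 43 with subtraction.

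Night libraries labelled per RNAi against control night, in which no loss of per was detectable and the printed level of per lay under the silent-gene limit, had 3 ecdysone synthesis genes lower again. The gene phm was at 12.8 against 253 RPKM (-4.20 and -2.75), sad at 131 against 883 (-2.74 and -1.27) and dib at 5.67 against 41.9 (-2.69 and -1.29), in all 5 scalings. In contrast nvd was at 6.42 against 2.21 RPKM (1.21 and 2.16), and the list's median of 0.27 lay at percentile 46.2 (from 0.55 to 62.9 over the settings) with 1 member past 4-fold higher and 3 lower as deposited, 2 and 1 on the abundant-gene scale, and 1 and 1 with subtraction. The member past 4-fold higher as deposited was spo, at 5.51 against 0.277 RPKM, near the silent-gene limit of 4.87 in these libraries. Ribosomal protein genes were low: 67 of 91 were past 4-fold lower and 0 higher as deposited (median -2.70, percentile 0), and 1 was higher and 11 lower on the abundant-gene scale (median -1.22). RpL41 was at 0.684 against 991 RPKM (-9.20 and -7.88), RpL37A at 0.296 against 521 (-8.65 and -7.39) and smt3, the SUMO gene, at 0.366 against 711 (-9.02 and -7.75); in the same condition other ribosomal protein genes had a median of 85.9 RPKM. Some larval serum and glue products were low too, with Fbp2 at 46.7 against 920 RPKM (-4.27 and -2.80), Lsp2 at 134 against 1105 (-3.03 and -1.56), Sgs7 at 32.4 against 1031 (-4.95 and -3.48) and Sgs8 at 8.61 against 312 (-5.03 and -3.58). The fat body list lay within the limits (median -1.60, percentile 41.2), with 1 member past 4-fold higher and 4 lower as deposited, and 1 and 1 on the abundant-gene scale. The salivary gland list had 5 of 8 members past 4-fold lower and 0 higher as deposited, at percentile 0, and 4 and 1 on the abundant-gene scale.

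Higher in those night libraries labelled per RNAi were Hsp70Bb, a heat-shock gene with near-identical copies, at 93.0 against 0.766 RPKM (5.73 and 6.41), His4:CG31611, at 300 against 3.19 (6.17 and 7.25), Dpt, the antimicrobial peptide diptericin, at 15.0 against 0.015 (3.98 and 4.25), and Pepck, the gluconeogenic enzyme, at 78.5 against 12.5 (2.56 and 3.90). The neuronal genes Snap25, at 7.91 against 0.755 RPKM, and Cha, at 9.98 against 1.48, were past 4-fold higher in a condition whose silent-gene limit was 4.87 RPKM. The midgut list (0.85, percentile 99.98) lay above random lists, with a median of -0.25 under median-ratio scaling. Altogether 1285 genes were past 4-fold higher and 419 lower as deposited, 107 and 1078 after median-ratio scaling, 99 and 250 after quantile normalization, 4176 and 189 on the abundant-gene scale and 1769 and 198 with subtraction.

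tim overexpression against control at night asks what more tim does. The ecdysone genes stayed near control, with sad at 633 against 883 RPKM (-0.48 and -0.08), phm at 258 against 253, and dib at 31.7 against 41.9 (-0.39 and 0.00), while sro, a short-chain dehydrogenase of the pathway, was at 54.0 against 27.9 (0.93 and 1.28). The list's median of 0.48 lay at percentile 98.2, down to 75.1 over the settings, with 0 members past 4-fold. Glue genes were high in all 5 scalings: Sgs7 at 8266 against 1031 RPKM (3.0 and 3.40), Sgs8 at 2418 against 312 (2.95 and 3.34), Sgs5 at 740 against 62.1 (3.55 and 3.93) and Sgs3 at 262 against 29.4 (3.12 and 3.46). In the salivary gland list 5 of 8 members were past 4-fold higher and 0 lower (median 2.5, percentile 100). Some gut proteases were high as well, with epsilonTry at 1287 against 122 RPKM (3.39 and 3.77), thetaTry at 167 against 13.0 (3.59 and 3.87) and Jon65Aiii at 1221 against 262 (2.22 and 2.61). The midgut list was at percentile 100 with a median of 0.51, but only 1 of its 13 members was past 4-fold higher and 0 lower.

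Antimicrobial genes were mixed under tim overexpression. Dpt was at 28.8 against 0.015 RPKM (4.88 and 4.12) and DptB at 24.6 against 0.033 (4.63 and 3.90), while IM4 was at 1.11 against 26.2 (-3.69 and -2.92) and Drs at 1.18 against 15.4 (-2.91 and -2.20). Lcp65Ab1, a larval cuticle protein with close copies, was at 0.236 against 198 RPKM (-7.33 and -6.26). The median of 11 hemocyte genes was negative in all 5 scalings (-0.69 as deposited, percentile 0.075), with He at 72.4 against 179 RPKM but 0 members past 4-fold. Also outside the limits were clock kinases (-0.48, percentile 1.06), the PTTH and MAPK pathway (-0.20, percentile 1.49), ecdysone response (0.23, percentile 2.23), DNA replication (-0.39, percentile 2.33) and innate immunity (0.16, percentile 98.5). The medians of PTTH and MAPK pathway, ecdysone response and innate immunity changed sign over the scalings. Each of these 5 lists came back within the limits under some setting, at percentiles of 5.24, 7.97, 7.84, 8.69 and 90.05 in the order given. With 68 genes past 4-fold higher and 28 lower, this comparison had the fewest of the 10 as deposited, and the split was 64 and 14 on the abundant-gene scale. A pseudocount of 0.1 ended that rank, with 2983 genes here and 886 for the added per.

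tim and per overexpression against control at night had high transcripts of the overexpressed tim and per, and ecdysone synthesis genes that went both ways. The core clock list lay within the limits (percentile 83.4), with 2 of 8 members past 4-fold higher, tim and per themselves. The gene dib was at 7.24 against 41.9 RPKM (-2.38 and -1.02), sad at 180 against 883 (-2.29 and -0.86) and phm at 62.2 against 253 (-2.01 and -0.59), lower in all 5 scalings. In contrast nvd was at 7.32 against 2.21 RPKM (1.37 and 2.29). Start1 was at 9.17 against 58.8 RPKM (-2.56 and -1.18) and sna at 4.91 against 26.4 (-2.21 and -0.89), each lower in the 5 scalings, as was Akh at 489 against 1517 (-1.63 and -0.20). The ecdysone list had 3 of 8 members past 4-fold lower and 0 higher as deposited, 0 and 1 on the abundant-gene scale, 0 and 0 with subtraction, and a median of 0.15 at percentile 89.1, and from 0.1 to 96.4 over the settings. Glue genes were low, Sgs7 being at 59.0 against 1031 RPKM (-4.11 and -2.68) and Sgs8 at 22.3 against 312 (-3.75 and -2.33), in a salivary gland list at percentile 0.02 with 4 of 8 past 4-fold lower as deposited and 2 on the abundant-gene scale. stg, the Cdc25 phosphatase that drives mitosis, was at 5.59 against 32.2 RPKM (-2.33 and -0.99).

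Higher with both clock genes overexpressed were toy, at 46.6 against 1.99 RPKM (3.99 and 4.90), Ste:CG33246, a multi-copy Stellate gene of the testis, at 26.2 against 0.053 (4.69 and 4.95), His4:CG31611, at 302 against 3.19 (6.18 and 7.22), and Su(Ste):CR42441, at 16.8 RPKM where control was listed at 0. The mitochondrially encoded ND5 was at 212 against 46.1 RPKM (2.17 and 3.56). Ribosomal protein genes were lower (median -1.56, percentile 0.135, 11 of 91 past 4-fold lower and 0 higher) and on the abundant-gene scale their median was -0.13, with 1 lower. Above random lists lay midgut (0.36, percentile 99.99), innate immunity (0.62, percentile 99.96), mitochondrial respiration (-1.0, percentile 99.95) and sterol uptake (0.04, percentile 98.98), and below them DNA replication (-0.83, percentile 0.62). Each of these 5 medians changed sign over the scalings, and innate immunity (73.2), sterol uptake (68.2) and DNA replication (8.59) came back within the limits under other settings. As deposited 268 genes were past 4-fold higher and 197 lower, against 141 and 808 after median-ratio scaling, 162 and 40 after quantile normalization, 738 and 17 on the abundant-gene scale and 198 and 34 with subtraction.

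**Figure D4:**
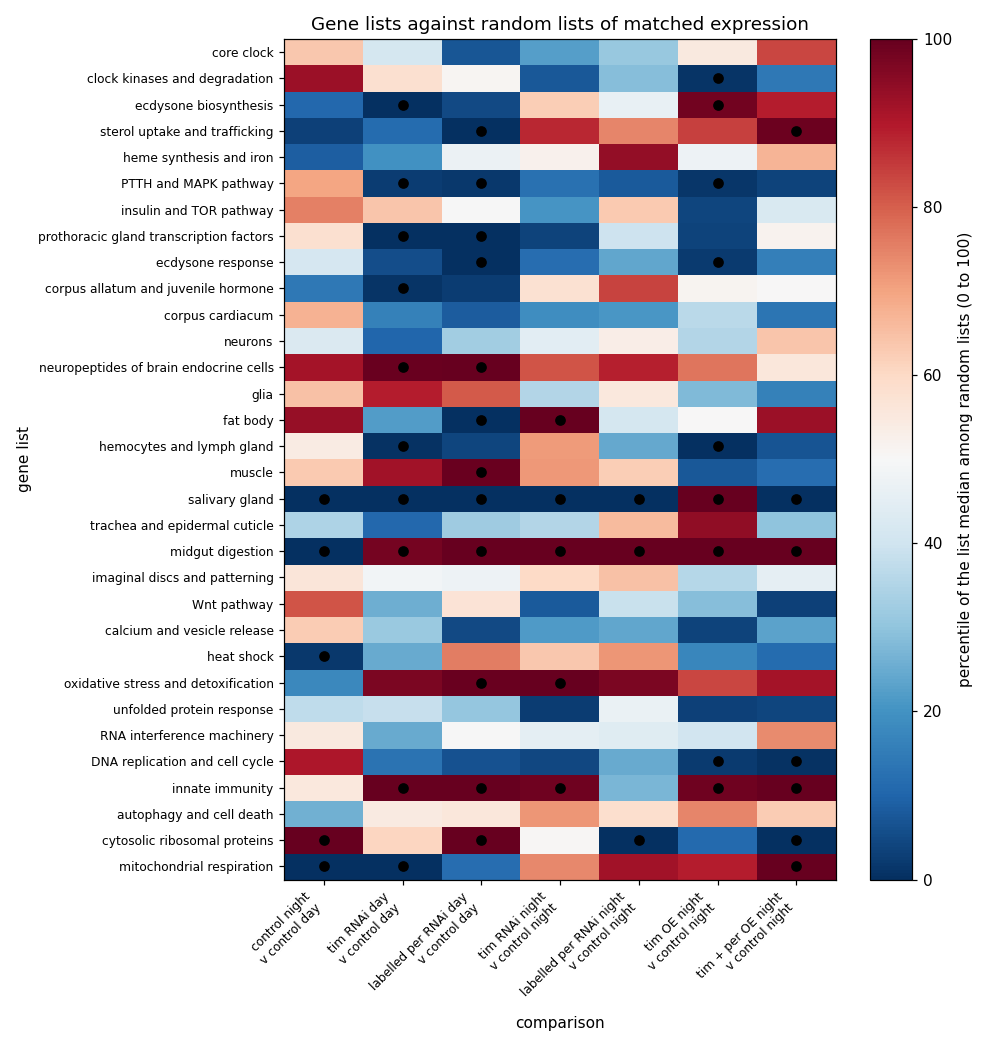
Percentile (colour, 0 to 100) of each of 32 list medians among 10000 random lists of matched expression, for the 7 comparisons on the x axis as deposited, with dots where it lay outside the central 95%. Dots mark 51 of 224 squares; the salivary gland and midgut lists have a dot in all 7 comparisons, and the signs of several list medians flip with the scaling.

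The remaining pairs set genotypes against each other. Within tim RNAi, night glands had more of the glue gene Sgs7, at 174 against 16.2 RPKM (3.35 and 4.21), and of Fbp2, at 900 against 98.5 (3.18 and 4.09), and far less of the immune-induced peptides IM2, at 0.008 against 153 (-7.26 and -6.55), and IM1, at 0.534 against 85.0 (-5.81 and -5.03). Cha was at 1.06 against 34.8 RPKM (-4.12 and -3.33). Within the libraries labelled per RNAi, Lsp2 was at 134 RPKM at night against 20.9 by day (2.62 and 2.81), Drs at 31.4 against 2.43 (3.24 and 3.45), Jon99Cii at 262 against 2858 (-3.44 and -3.26) and RpL37A at 0.296 against 183 (-7.15 and -7.17). Adding per to tim overexpression went with Sgs7 at 59.0 against 8266 RPKM (-7.11 and -6.08), Sgs5 at 14.4 against 740 (-5.59 and -4.58), phm at 62.2 against 258 (-2.03 and -1.01), Dpt at 2.92 against 28.8 (-2.93 and -1.99) and AttC at 1.97 against 23.6 (-3.05 and -2.14). Directions in these sentences held in the 5 scalings.

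Past 4-fold in these 3 pairs were 20 genes higher and 361 lower within tim RNAi, 1133 and 270 within the libraries labelled per RNAi, and 68 and 60 for the added per. For tim RNAi the split was 55 and 165 after median-ratio scaling, 38 and 162 after quantile normalization, 40 and 183 on the abundant-gene scale and 41 and 203 with subtraction. For the libraries labelled per RNAi it was 40 and 748 after median-ratio scaling and 57 and 329 after quantile normalization, but 1967 and 269 on the abundant-gene scale and 868 and 287 with subtraction. For the added per it was 40 and 89, 89 and 34, 213 and 20, and 139 and 31 in the same order as for tim RNAi.

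The night-minus-day difference of the ecdysone genes depended on genotype in a way that depended on scale. As deposited, sad was 3.86 higher at night in control and 0.40 in tim RNAi, a double difference of -3.46, and on the abundant-gene scale the values were 0.93 and 1.28, a double difference of 0.35. For phm the double difference of tim RNAi was -2.52 as deposited and 1.25 scaled, and for dib -2.91 and 0.62. In the libraries labelled per RNAi, phm was 1.47 log2 units lower at night than by day (-1.47 as deposited and -1.30 scaled), and its double difference stayed negative, at -4.50 and -1.42. For sad and dib in those libraries the double differences flipped, from -2.32 to 0.79 and from -1.54 to 1.41.

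Shared genes between comparisons were counted against the number that independent lists would share. By day, tim RNAi and the libraries labelled per RNAi shared 281 genes past 4-fold higher, where independent lists would share 18.8, and 32 lower, where they would share 0.492. Sgs7, Sgs8, Sgs3 and Jon65Aiv were among those named above. At night they shared 62 lower genes (5.87 for independent lists), sad, phm and dib included, and 10 higher (2.10) as deposited, and 13 lower (0.5) and 36 higher (26.0) on the abundant-gene scale, where sad and dib were no longer shared. Overexpression of tim and of both genes had 20 higher (1.42) and 19 lower genes (0.43) in common, among them Lcp65Ab1. The pair of tim RNAi and tim overexpression at night shared 11 higher and 21 lower genes (0.111 and 0.392). These pairs share their control libraries, which raises such counts by construction, and with 1 average per condition the controls could not be split or simulated. The numbers for independent lists also take all 12843 genes as equally likely to pass. By day, 654 of 739 higher genes of tim RNAi and 303 of 326 of the other were among the 3227 of mean RPKM at least 5. The 18.8 is therefore too low for that reason as well. On the abundant-gene scale the day pair shared 50 higher (0.69) and 1985 lower genes (1012). In pairs with separate controls, tim RNAi by day and at night shared 1 higher gene (1.21) and 11 lower (0.715), and the libraries labelled per RNAi shared 9 (32.6) and 14 (4.05), while 34 genes and 161 genes went in opposite directions. On the abundant-gene scale tim RNAi shared 10 higher (0.673) and 19 lower (6.34) genes between day and night, and the libraries labelled per RNAi 13 (26.7) and 29 (79.9), with 31 genes and 2058 genes in opposite directions. No number for independent lists was computed for opposite directions. With 5428 genes lower by day and 4176 higher at night in the libraries labelled per RNAi, independent lists would also share many, so the 2058 cannot be read as a reversal.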

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

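Abundant-gene scaling, its use after subtracting the silent-gene level, and its use with the stricter filter were chosen after the data had been seen; the other alternatives were fixed before. No paired analysis was possible because the table holds only 1 average per condition. For the same reason the replicate block, fits of 2 groups alone, fits without a trend, leaving out each replicate, other list tests and counts of interactions were not run. Without a filter the 10 counts of genes past 4-fold were the same by construction, because genes under 1 RPKM everywhere cannot differ 4-fold with a pseudocount of 1. Over all alternatives, 31 of 80 values of these counts, the 10 without a filter included, stayed within 1.5 times the deposited one and 49 did not. Differences of tim, per and ecdysone genes moved by at least 1.5-fold in 159 values, stayed closer in 218 and, among differences past 4-fold as deposited, changed direction in 3. Of those 218, 56 without a filter and 22 with a mean RPKM of at least 5 could not move, because a filter leaves a gene's own difference as it is. Smaller differences that changed sign, such as those of sro in control night against day and of tim in tim RNAi night, are counted by how far they moved. List percentiles outside the limits stayed outside on the same side in 322 values, 50 of them without a filter, and came back within in 78.

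In the order control night against day, tim RNAi day, labelled per RNAi day, tim RNAi night, labelled per RNAi night, tim overexpression, tim and per overexpression, tim RNAi night against day, labelled per RNAi night against day, and added per, a pseudocount of 0.1 gave 4739, 1820, 2837, 2310, 5083, 2983, 5075, 1579, 6010 and 886 genes, where a pseudocount of 1 gave 1120, 790, 450, 201, 1704, 96, 465, 381, 1403 and 128. A smaller pseudocount widens differences between low values by construction. On the abundant-gene scale the counts were 7494, 2502, 5510, 114, 4365, 78, 755, 223, 2236 and 233. With the silent-gene level subtracted as well, control night against day gave 2440, tim RNAi day 2027, labelled per RNAi day 1324, tim RNAi night 117, tim and per overexpression 232 and tim RNAi night against day 244. With abundant-gene scaling and a mean RPKM of at least 5, the counts were 662 for control night against day, 91 for tim RNAi night, 651 for labelled per RNAi night, 63 for tim overexpression, 174 for tim and per overexpression, 173 for tim RNAi night against day and 563 for labelled per RNAi night against day.

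Quantile normalization gave 345 genes for control night against day, 448 for tim RNAi day, 90 for tim RNAi night, 349 for labelled per RNAi night, 63 for tim overexpression, 202 for tim and per overexpression, 200 for tim RNAi night against day and 386 for labelled per RNAi night against day. Median-ratio scaling gave 796 for labelled per RNAi day, 949 for tim and per overexpression, 220 for tim RNAi night against day and 788 for labelled per RNAi night against day. A mean RPKM of at least 5, which left 3227 genes, gave 457 for labelled per RNAi night, 62 for tim overexpression, 258 for tim and per overexpression, 436 for labelled per RNAi night against day and 83 for added per. The difference of dib between control night and day, 2.44 as deposited, was -0.33 on the abundant-gene scale, -0.18 with subtraction as well and -0.33 with the stricter filter. The cause of these moves, apart from the pseudocount and the smaller number of genes, was not tested. The unknown read depth limits what can be said of genes under the silent-gene level, tim and per by day included.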

Other observations

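All 8 tests in this part were chosen after the result they bear on had been seen. Some lists of neighbouring cell types and pathways, a few of them mentioned above, are summarized first. Insulin and TOR pathway (percentiles 4.29 to 75.3 over the 7 comparisons), heme synthesis and iron (8.89 to 93.8), corpus cardiacum (8.23 to 67.4), neurons (10.2 to 63.9), glia (16.1 to 89.4) and the core clock (7.04 to 83.4) lay within the limits in all 7 as deposited. So did trachea and epidermal cuticle (10.6 to 94.4), imaginal discs (35.9 to 64.5), the Wnt pathway (3.28 to 81.5), calcium and vesicle release (3.70 to 62.8), the unfolded protein response (2.58 to 46.6), RNA interference machinery (24.9 to 73.6) and autophagy (26.0 to 74.5). Other settings put some of them outside: calcium (0.57), the core clock (0.98) and corpus cardiacum (1.83) in the day libraries labelled per RNAi, heme (97.9) in the night ones, the unfolded protein response in tim RNAi night (1.82), and imaginal discs (0.06), neurons (2.37), trachea (98.5) and the unfolded protein response (2.13) in tim overexpression. The Thor gene, a translation inhibitor repressed by insulin signalling, was at 101 RPKM in control night, 27.8 in tim RNAi night and 23.8 in tim and per overexpression, lower in all 5 scalings in both. Xbp1, a factor of the unfolded protein response, was at 20.0 RPKM in tim RNAi night against 65.3 (-1.66 as deposited and -0.29 on the abundant-gene scale). Among neurohormones, Eh was at 5.62 RPKM in the night libraries labelled per RNAi against 0.004 in control night, and Ptth, which drives the prothoracic gland, at 2.65 in tim RNAi day against 0.06, each near the silent-gene limit of its condition, and the control values lie in the uncertain group under 0.2 RPKM.

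The level of silent genes differed between conditions, from a chemoreceptor median of 0.006 RPKM in control night to 1.99 in tim and per overexpression. A plain difference of scale is argued against, because the ratio of ribosomal protein to chemoreceptor medians differed 2940-fold between control night and control day. The size of that contrast is uncertain, since the control night median of 0.006 RPKM lies in the uncertain group under 0.2 RPKM. Among conditions with raised silent genes the ratio still ran from 37.4 in control day to 689 in tim overexpression. The genes taken next as silent were picked on control night values, which are uncertain in the same way. Among genes under 0.3 RPKM in control night, 635 X-linked and 3403 autosomal, the X over autosome ratio of medians (95% bootstrap interval) in the 6 conditions with raised silent genes was 0.829 (0.764 to 0.879) in control day, 0.809 (0.755 to 0.853) in tim RNAi day, 0.81 (0.778 to 0.844) in tim RNAi night, 0.7645 (0.666 to 0.859) in the night libraries labelled per RNAi, 0.746 (0.712 to 0.794) in tim overexpression and 0.753 (0.716 to 0.773) in tim and per overexpression. Genomic DNA among the reads stays open: 3 of the 6 intervals include the 0.75 of a sample with as many males as females and 3 lie above it, up to a lower end of 0.778, while the sex ratio of the larvae is not known. Low transcription of these genes stays open too, because compensated RNA would give 1, above the highest upper end of 0.879, but RNA of silent X-linked genes may not be compensated.

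A separate group of values between 0 and 0.2 RPKM, 2363 protein-coding genes in control night and 176 in tim and per overexpression, held values of well-used genes. Single reads on long genes are argued against, because the low group was shorter than the genes above it in 7 of 8 conditions, with median exon lengths of 818 against 1895 bases in control day. The contrast was small in control night, where the group was largest, at 1752 against 1989 bases. In tim and per overexpression it went the other way, at 1915 against 1796. Geometric averaging of 2 libraries with 0 replaced by a constant stays open: squaring the low values and dividing by the constant gave a level that was 0.6 times the most common level of the condition in the median, although from 0.104 to 2.96 over conditions. Under that hypothesis RpL41, at 0.684 RPKM in the night libraries labelled per RNAi, may stand for 1 library at 0 and another near 2052 RPKM. No biological explanation was tested.

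Antimicrobial peptide genes were high in tim RNAi day, with an innate immunity median of 2.12 on the abundant-gene scale (quartiles 0.71 and 2.75). On that scale the upper quartile of the fat body list was 0.40, although Lsp1beta reached 2.00, which argues against more fat body tissue in the dissection. As deposited, 6 of 9 fat body members were past 4-fold higher and 0 lower, with a median of 2.14 against 3.55 for innate immunity. The answer depends on the scale, so more fat body tissue stays open. More gut tissue stays open as well. On the abundant-gene scale the day libraries labelled per RNAi had the midgut list at 0.45, above the -0.38 of tim RNAi day, and an innate immunity median of -1.24. As deposited both midgut medians were 1.98, and the innate immunity median of those libraries was 0.09. The comparison cannot decide, because it takes gut to carry the same immune transcripts in both genotypes, which was not tested. A response to tim RNAi present at both times, weaker at night, stays open, because the answer depends on the scale. On the abundant-gene scale 2 members were past 4-fold higher and 1 lower at night, and 11 higher and 1 lower by day. On that scale the upper quartile at night, 0.87, lay above the lower quartile by day. As deposited 0 were past 4-fold higher and 2 lower at night, and 15 higher and 0 lower by day. The median at night ran from -0.27 as deposited to 0.71 on the abundant-gene scale, where that of all genes was 0.45. An immune response in a part of the day animals, or a response to tim RNAi by day alone, may explain the pattern and was not tested, because the averages do not show the 2 libraries apart.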
